A study of Mus musculus with 2 samples.

How the data were processed

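Long-bone marrow of untreated C57BL/6 mice was profiled by droplet single-cell RNA sequencing. The mice carried either 2 wild-type Cxcr4 alleles (Cxcr4+/+) or 1 copy of the WHIM allele (Cxcr4WHIM/+). Per the labels, flushed marrow and bone chips were digested with collagenase IV, and cells without CD45, Ter119, CD71 and lineage antigens were sorted through a LEPR gate and through a CD31 and CD144 gate. Both gates were collected in 1 tube, so no label parts LEPR-gated from CD31- and CD144-gated cells. Cells of 2 mice were pooled per genotype, and 1 library per genotype was made with Chromium 3′ v3.0 chemistry, sequenced on a NovaSeq and aligned to GRCm38 (mm10).

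The deposited matrices hold the UMI count of each of 31053 genes in each called cell. The authors made them with Cell Ranger, version 4.0 according to their processing notes and version 5.0.1 per the file headers. The annotation release behind the files, and whether counting used the strand, are not given in the sources used here. Of the gene IDs, 30934 (99.6%) were found in GENCODE M21 (GRCm38), 30468 of them with the same symbol, and coordinates are from that release. Where a symbol stood for several IDs (71 features), the ID with the most counts kept the symbol.

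The Cxcr4+/+ library held 10018 cells and 37442000 UMIs, and the Cxcr4WHIM/+ library 10819 cells and 56519139 UMIs (ratio 1.51). The median cell had 2979 and 4404 UMIs, and the mitochondrial share was 2.59 and 2.70% of UMIs. Cells with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were retained (9520 and 10373). Scrublet (in scanpy 1.11.5, expected rate 0.08, each library alone) called 353 (3.71%) and 229 (2.21%) of them doublets, and these were removed. The 9167 and 10144 kept cells were clustered together: scaling to 10000 UMIs per cell, logarithm, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1. Niche factors, interferon-stimulated, immediate early, heat shock, ribosomal, mitochondrially encoded and haemoglobin genes, Xist and Y-linked genes were left out of the variable genes, so that these genes did not form the clusters. The other compared lists, acute phase and complement among them, stayed eligible as variable genes and may have shaped the clusters. No batch correction was used, because library and genotype are the same split.

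Each of the 26 clusters was scored on 20 marker lists by the mean log2 fold of the list's genes over the median of all clusters. The cluster took the name of its best list if at least 3 of that list's markers were detected in at least 25% of its cells and no other list had more members among its 10 leading genes. The classes compared were MSC-like (mesenchymal stromal), endothelial-like and osteolineage-like cells. Clusters whose best list was haematopoietic progenitor, 3 of them too mixed for a name, were pooled as haematopoietic progenitor clusters, a class added after the data were seen. Clusters without a name (11, 12, 13 and 19) held 20.5% of Cxcr4+/+ and 10.4% of Cxcr4WHIM/+ kept cells.

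UMIs of a class were summed per library and expressed as CPM, relative to all UMIs of that class. With 1 library per genotype there was no replicate spread, and no test between genotypes was made. Values carry exact 95% Poisson intervals, ratios (Cxcr4WHIM/+ over Cxcr4+/+) exact conditional intervals and shares exact binomial intervals; these hold counting error only. Genes with at least 50 UMIs in the class over both libraries were measured (11825 in MSC-like, 4184 in endothelial-like, 8697 in osteolineage-like cells and 11613 in the haematopoietic progenitor clusters). Genes were ranked by the bound of the ratio's interval nearest 1. Ranking was not bound to the 50 UMIs: a ranked gene had to reach 50 CPM in at least 1 library and to lie on 1 side of 1 in every cluster of the class with at least 100 cells in each library, and 12 genes per direction were named. Ribosomal, mitochondrial, haemoglobin, immunoglobulin, sex-linked and blood marker genes and unnamed gene models were not ranked. All measured members of the Cxcr4 axis and niche lists could be named, and up to 4 of each of the other fixed lists, 30 in all.

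A list member was called higher or lower if its ratio passed 1.5-fold with an interval that excluded 1. Median log2 ratios (0.5 counts added) were set against 10000 random lists of the same size drawn from 20 expression bins, with 2.5 to 97.5% as the range, as a description of these libraries. Shares of cells with a UMI were also computed after thinning each cell to 2000 UMIs and leaving out cells below that. The gene and marker lists, classes, thresholds and most alternatives were fixed before the data were examined. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.

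The counting steps were tested on simulated data, with counts drawn at the observed depth and 200 changed genes. Intervals covered the true ratio for 95.5% of genes at MSC-like depth and 96.0% at endothelial-like depth, and 0.491 and 2.45% of unchanged genes were called. At a true fold of 1.5, 86 and 54% of changed genes were called on the right side, and at a fold of 2, 100 and 96%. Lists without a change lay outside the random range in 5.5 and 3.2% of 1000 draws. A list of 20 genes changed by 1.5-fold had a median fold of 1.45 and 1.44. Simulated sums were Poisson draws, the model behind the intervals, so coverage near 95% was built in. They carry no difference between mice or tubes and no added spread between cells. Intervals on the real counts may therefore be too narrow, which the simulation could not check.

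Alternatives were 500 UMIs with 200 genes, 2000 UMIs, 5 and 20% mitochondrial UMIs, no doublet removal, resolutions 0.5 and 2, no list left out of clustering, minima of 1 and 200 summed UMIs, edgeR's trimmed mean of M values (TMM), median of ratios, totals without mitochondrial, ribosomal and haemoglobin genes, the mean over cells, clusters weighted by their mean share, and thinned cells. Of the scalings, none moved a median by more than 0.0433 (log2). A run without cells carrying MSC transcripts (at least 2 of Adipoq, Lepr, Cxcl14 and Hp) and weighting of the osteolineage clusters were added after the results had been seen. Carrying cells were flagged on unthinned counts, so a deeper cell was flagged more readily.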

Results

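Marrow stromal cells of the Cxcr4WHIM/+ library held more C3 transcript and less Socs2, Cxcl1 and Hspb1 transcript than those of the Cxcr4+/+ library, while Cxcl12 was nearly equal. The WHIM allele changes the receptor for Cxcl12, the chemokine that holds blood stem and precursor cells in marrow. Values below are given for Cxcr4+/+ and then Cxcr4WHIM/+, in CPM of the class, followed by the ratio of Cxcr4WHIM/+ over Cxcr4+/+ and, for leading genes, its interval. Each genotype was 1 library of 2 pooled mice from 1 tube, so genotype cannot be told apart from library or tube, and intervals hold counting error only.

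Of the kept cells, sorted as CD45-, Ter119-, CD71- and lineage-negative cells through the LEPR or the CD31 and CD144 gate, MSC-like cells made up 53.2% (52.2–54.3) and 59.7% (58.8–60.7). This order turned in 4 alternative settings (53.6 and 50.4% at 5% mitochondrial UMIs, for example), in each of which a cluster with MSC as its best list stayed unnamed. These cells carried all 10 MSC markers in each of their 7 clusters (0, 2, 3, 4, 6, 8 and 16). Endothelial-like cells were 2.69% (2.37–3.05) and 2.08% (1.81–2.38), and osteolineage-like cells 4.27% (3.86–4.70) and 6.02% (5.57–6.50). Smaller groups were chondrocyte-like (1.03 and 0.355%), fibroblast-like (0.764 and 0.976%), neutrophil-like (0.676 and 1.14%), megakaryocyte-like (1.24 and 1.58%), T- and NK-like (0.524 and 0.542%), plasma-cell-like (0.240 and 0.286%) and erythroid-like cells (0.273 and 0.355%). The gates and the digestion set these shares, which do not measure abundance in the marrow. Clusters 3 and 6 held 71.6% of Cxcr4+/+ and 15.2% of Cxcr4WHIM/+ MSC-like cells, and clusters 2 and 4 held 13.8 and 71.0%. With 1 library per group, a cluster mostly of 1 library may be that library, not a type.

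In MSC-like cells Cxcr4 itself was close to background at 2.47 and 2.93 CPM (1.19, 0.772–1.86), and a 3′ count cannot show the mutated residues or check a label. Cxcl12, by contrast, was detected in 100% of these cells and stood at 26471 and 26947 CPM (1.02, 1.01–1.02). The stem cell factor gene Kitl was 1179 and 1335 CPM (1.13, 1.11–1.15), and the lymphoid cytokine gene Il7 75.9 and 69.5 CPM (0.915, 0.846–0.991). Among the other niche factors, Igf1 (512 and 373 CPM, 0.729, 0.707–0.753), Angpt1 (162 and 112 CPM, 0.692, 0.654–0.733), Il15 (61.5 and 40.1 CPM, 0.651, 0.593–0.716), Il34 (571 and 463 CPM, 0.811), Csf1 (461 and 417 CPM, 0.904) and Vcam1 (1466 and 1360 CPM, 0.928) were lower. Tnfsf13b, which encodes the B cell survival factor BAFF, was higher at 5.70 and 13.98 CPM (2.45, 1.90–3.20), as was the heparin-binding growth factor gene Ptn at 13.1 and 21.4 CPM (1.63, 1.37–1.95). Fgf7 was 92.6 and 117 CPM (1.27). Of 21 measured niche factors, 2 were higher by 1.5-fold (Tnfsf13b, Ptn), 1 lower (Il15) and 18 neither, with a median log2 ratio of −0.15 at percentile 1.83 of random lists. The Cxcr4 axis list had 0 of 6 members past 1.5-fold (median 0.06, percentile 75.3), with Ackr4 at 179 and 216 CPM (1.21), Hmgb1 at 502 and 393 CPM (0.782), Mif at 214 and 191 CPM (0.894) and Cd74 at a ratio of 1.07.

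The leading genes of MSC-like cells differed more. C3, the central complement component, was 655 and 2113 CPM (3.22, 3.15–3.30), and it is also among the leading genes of clusters 2 and 4, the ones mostly of Cxcr4WHIM/+ cells. A C3 UMI was found in 53.4 and 87.7% of cells, and in 49.7 and 82.7% after thinning, which left out 1297 and 344 cells (median depth 2492.5 and 3800.5 UMIs). The haematopoietic progenitor clusters gave a thinned share of 1.89 and 3.99% as background. Also higher were the growth-arrest gene Gadd45a (25.8 and 79.9 CPM, 3.10), the granule proteoglycan gene Srgn (44.1 and 133 CPM, 3.01), the transcriptional repressor gene Bcl6 (23.6 and 66.7 CPM, 2.83), Tmem86a (111 and 303 CPM, 2.72), the calcium-binding S100a6 (253 and 563 CPM, 2.23), the aggrecanase gene Adamts5 (57.7 and 119.8 CPM, 2.07), the tight junction gene Cldn1 (58.3 and 114 CPM, 1.95), Dcn (218 and 409 CPM, 1.88), Fhl2 (205 and 384 CPM, 1.87) and Lars2 (56.2 and 104 CPM, 1.86). With clusters weighted by mean share, Tmem86a was 1.73, S100a6 1.42 and Adamts5 1.23, so these differences went partly with the clusters that filled each library. Clusters 2, 3, 4 and 6 were each mostly of 1 library. The weighting therefore cannot tell a mix of cell types from a library-wide difference. Across all alternatives Dcn came down to 1.26, Cldn1 to 1.39 and Fhl2 to 1.61, while Gadd45a stayed at 2.32 or more and Lars2 at 1.81 or more. AY036118 was 442 and 1268 CPM (2.87); it is an annotated noncoding RNA overlapping ribosomal RNA sequence, and it was higher in the other classes too (3.26 in endothelial-like, 2.92 in osteolineage-like cells, 4.99 in the haematopoietic progenitor clusters).

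Lower in Cxcr4WHIM/+ MSC-like cells were Socs2, a suppressor of cytokine signalling (130.2 and 40.5 CPM, 0.311, 0.287–0.336), the neutrophil chemokine gene Cxcl1 (99.5 and 36.8 CPM, 0.370, 0.340–0.403), the small heat shock protein gene Hspb1 (438 and 187 CPM, 0.426, 0.410–0.443) and the anion exchanger gene Slc26a7 (404 and 164 CPM, 0.406). Apod (196 and 88.5 CPM, 0.452), Map1b (69.6 and 31.2 CPM, 0.449), Ier3 (239 and 117 CPM, 0.490), Ptpn1 (203 and 102 CPM, 0.503), the activin receptor gene Acvr2a (71.0 and 34.3 CPM, 0.484) and the BMP-binding Bmper (52.3 and 25.3 CPM, 0.484) followed. Across all alternatives Ier3 came up to 0.722 and Apod to 0.576, while Map1b stayed at 0.457 or less and Bmper at 0.493 or less. Hspa1b (77.8 and 29.7 CPM, 0.383) is nearly identical to Hspa1a, so the split between them is uncertain. Snhg9 (58.1 and 19.3 CPM, 0.333) is annotated antisense, and it was also lower in osteolineage-like cells (0.260) and the haematopoietic progenitor clusters (0.322). By the ranking rule, each of these named genes lay on 1 side of 1 in clusters 0, 2, 3, 4, 6 and 8. Cluster 16 had too few cells to check. Cluster 8 was led by Cxcl1, Serpine1, Ccl2, Ccl7, Mt2, Mt1 and Fosb, and cluster 16 by Cxcl10, Cxcl9, Iigp1, Gbp2 and Ifit3.

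**Figure D1:**
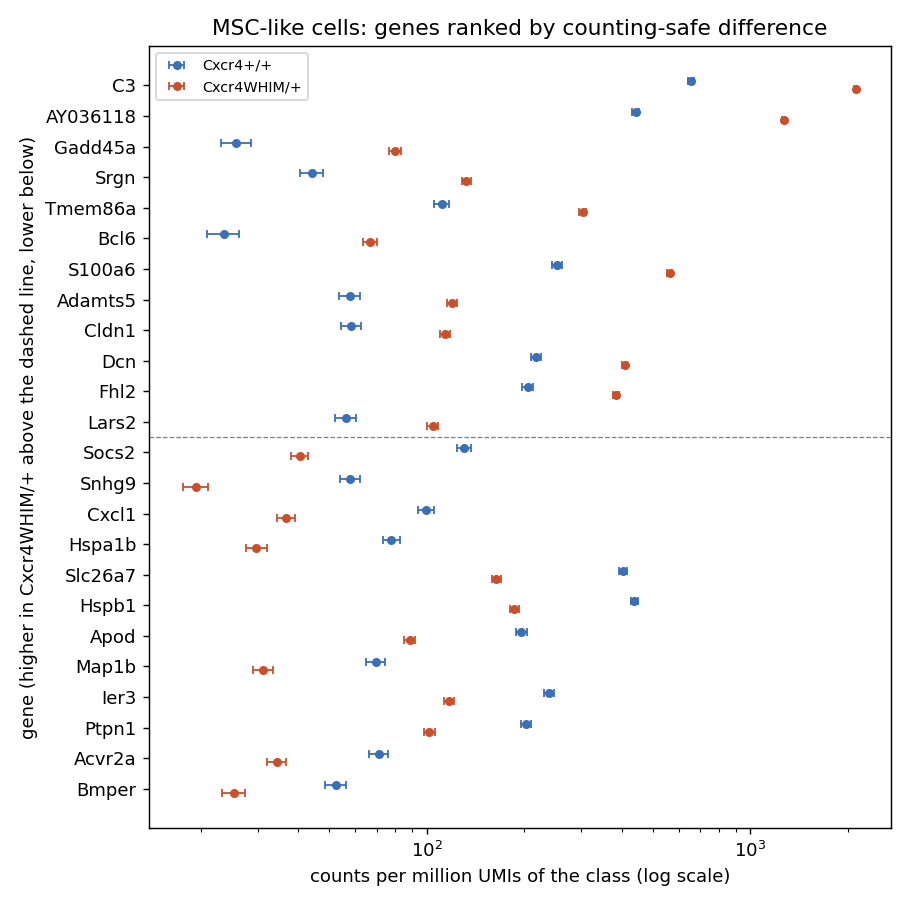
Expression of 24 named genes in MSC-like cells of the Cxcr4+/+ and the Cxcr4WHIM/+ library. Dots are CPM summed over the cells of 1 library, on a logarithmic axis; bars are exact 95% Poisson intervals, which hold counting error only.

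By group, 3 of 30 lists lay above and 9 below the range of random lists in MSC-like cells. Acute phase and complement genes were above (19 measured, 5 higher and 0 lower, median 0.28, percentile 100), with Lrg1 at 14.9 and 42.2 CPM (2.84), Saa3 at 29.4 and 67.0 CPM (2.28) and Il1rn at 298 and 504 CPM (1.69) beside C3; Il1rn and Hp also led the mostly Cxcr4WHIM/+ clusters. Lymphotoxin beta receptor and noncanonical NF-kB genes, pathway components among them, were above as a group (2 higher, 0 lower and 13 neither, median 0.13, percentile 98.4). The members past 1.5-fold were the follicular chemokine gene Cxcl13 (3.62 and 28.5 CPM, 7.88, 5.86–10.8) and Tnfsf13b. Ribosomal protein genes had a median of 0.12 (percentile 100) with 92 of 93 neither and Rpl36al lower (0.656).

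Stress and inflammatory groups were lower. Heat shock genes had 0 higher, 6 lower and 9 neither (median −0.55, percentile 0), among them Hspb1, Hspa1a (79.2 and 34.6 CPM, 0.437) and Dnajb1 (237 and 144 CPM, 0.608). TNF and canonical NF-kB targets had 1 higher, 6 lower and 13 neither (−0.25, percentile 0.21), with Cxcl1, Cxcl2 (6.94 and 1.46 CPM, 0.211), Ptgs2 (3.01 and 0.691 CPM, 0.230) and Ccl7 (119 and 58.6 CPM, 0.492). Immediate early genes had 0 higher, 6 lower and 19 neither (−0.29, percentile 0), with Ier3, Fos (1881 and 1246 CPM, 0.663), Fosb (894 and 577 CPM, 0.645) and Nr4a1 (111 and 71.0 CPM, 0.639). Glucocorticoid and circadian genes had 1 higher, 7 lower and 12 neither (−0.42, percentile 0), with the metallothionein genes Mt1 (1729 and 925 CPM, 0.535) and Mt2 (327 and 184 CPM, 0.561) and the clock gene Nr1d2 (89.2 and 46.9 CPM, 0.526). Unfolded protein response genes were lower as a group (−0.24, percentile 0.09) with 0 of 20 past 1.5-fold and Ddit3 at 0.736.

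Of the signalling and matrix groups, Notch signalling was below the range (0 higher, 3 lower, 8 neither, median −0.34, percentile 0.15), with Notch2 at 478 and 291 CPM (0.609) and Lfng at 49.4 and 32.8 CPM (0.665). BMP and TGF-beta signalling had 0 higher, 1 lower and 26 neither (−0.15, percentile 1.70), with Skil at 103 and 66.4 CPM (0.645) and the BMP antagonist gene Grem1 at 408 and 279 CPM (0.683). Sinusoidal scavenger and coagulation genes were below too (0 higher, 3 lower and 7 neither, −0.43, percentile 0.12), with Procr at 6.86 and 4.14 CPM (0.604), and summed pan-endothelial markers in these cells stood at 70.9 and 60.8 CPM. Inside the range were interferon-stimulated genes (0 of 31 past 1.5-fold, 0.01), MHC class I (0.02) and class II (0.20), p53 targets (−0.02), adipogenic genes (−0.08; Lpl 1.30, Apoe 0.796), osteogenic genes (−0.06), fibrillar collagens and matrix (5 higher, 4 lower and 23 neither, 0.05; Col6a3 24.0 and 51.8 CPM, 2.15), basement membrane (−0.05), Wnt signalling (3 higher, 1 lower and 16 neither, 0.06; Sfrp1 115 and 187 CPM, 1.63), endothelial adhesion (−0.06), VEGF and angiopoietin signalling (−0.06), hypoxia and glycolysis (0.01), oxidative phosphorylation (−0.05), cholesterol synthesis (−0.06), S phase (−0.13), G2 and M phase (−0.07) and mitochondrially encoded genes (0.02). Of other cells' transcripts in this class, summed fibroblast markers were 240 and 363 CPM, haemoglobin genes 246 and 350 CPM and plasma cell markers 51.7 and 20.6 CPM.

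Part of these differences went with the clusters that filled each library. With MSC-like clusters weighted by their mean share, heat shock genes (−0.44), glucocorticoid and circadian genes (−0.25), unfolded protein response genes (−0.23), sinusoidal scavenger genes (−0.36), BMP and TGF-beta signalling (−0.16) and ribosomal protein genes (0.10) stayed outside the random range. Immediate early genes (0.00504), TNF targets (−0.13), Notch signalling (−0.09), niche factors (−0.08), lymphotoxin beta receptor genes (0.02) and acute phase genes (0.11, percentile 96.8) lay inside it. Single genes kept larger ratios under this weighting, among them Bcl6 (3.35), C3 (2.29), Srgn (2.11), Hspb1 (0.498) and Cxcl1 (0.547), while Ptn was 1.04.

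Endothelial-like cells (247 and 211 cells) formed cluster 14, with 10 pan-endothelial and 9 of 10 sinusoidal markers, and cluster 15, with 10 pan-endothelial and 5 of 13 arterial markers. Cluster 14 held 50.6% (44.2–57.0) and 41.7% (35.0–48.7) of them. Cxcr4 was 29.8 and 53.5 CPM (1.79, 0.971–3.43), found in 4.45 and 6.16% of cells (3.82 and 5.07% after thinning, 116 and 73 cells left out, median depth 2058 and 2513 UMIs). The thinned share in MSC-like cells was 0.391 and 0.385%. Nearly all of its endothelial UMIs lay in cluster 15 (16 and 33, ratio 1.69, 0.905–3.29), with 1 and 0 in cluster 14. The atypical Cxcl12 receptor gene Ackr3 was 24.6 and 81.1 CPM (3.30, 1.80–6.46), Cd74 28.1 and 68.1 CPM (2.43, 1.34–4.62) and the chemokine-binding Ackr1 584 and 435 CPM (0.744, 0.631–0.876). The axis list was above the random range (7 measured, 2 higher and 0 lower, median 0.38, percentile 99.3), yet inside it without cells carrying MSC transcripts (0.13, percentile 86.9). Of 13 niche factors 1 was higher, Bmp6 (40.4 and 102 CPM, 2.53, 1.55–4.28, but 1.08 in thinned cells and 1.64 without doublet removal), and 12 neither (0.14, percentile 92.5), with Vcam1 at 944 and 764 CPM (0.809) and Jag1 at 137 and 94.1 CPM (0.687).

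Cxcl12 in endothelial-like cells was 2517 and 3276 CPM (1.30, 1.22–1.39), with opposite directions by cluster (6.45 in cluster 14, 0.440 in cluster 15). Summed MSC markers were 1536 and 2257 CPM there, and 13.4% (9.38–18.2) and 18.0% (13.1–23.9) of the cells carried at least 2 of Adipoq, Lepr, Cxcl14 and Hp. Without these cells Cxcl12 was 780.3 and 751 CPM (0.962, 0.828–1.12) and Kitl, 230 and 319 CPM (1.39, 1.11–1.75) with them, had a ratio of 1.22 (0.920–1.62). Cxcl12 was then 0.858 (0.614–1.19) in cluster 14 and 0.871 (0.734–1.03) in cluster 15. Lepr (0.271, 0.0654–0.850, on 15 and 4 UMIs) and Adipoq (0.185, 0.0199–0.846, on 11 and 2 UMIs) were under 1 afterwards. The values without carrying cells may therefore hold unequal removal. C3 was 50.9 and 209 CPM (4.11, 2.73–6.38), 11.4 in cluster 14 and 1.68 in cluster 15, and 4.31 (1.41–17.6) on 4 and 17 UMIs without carrying cells.

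**Figure D2:**
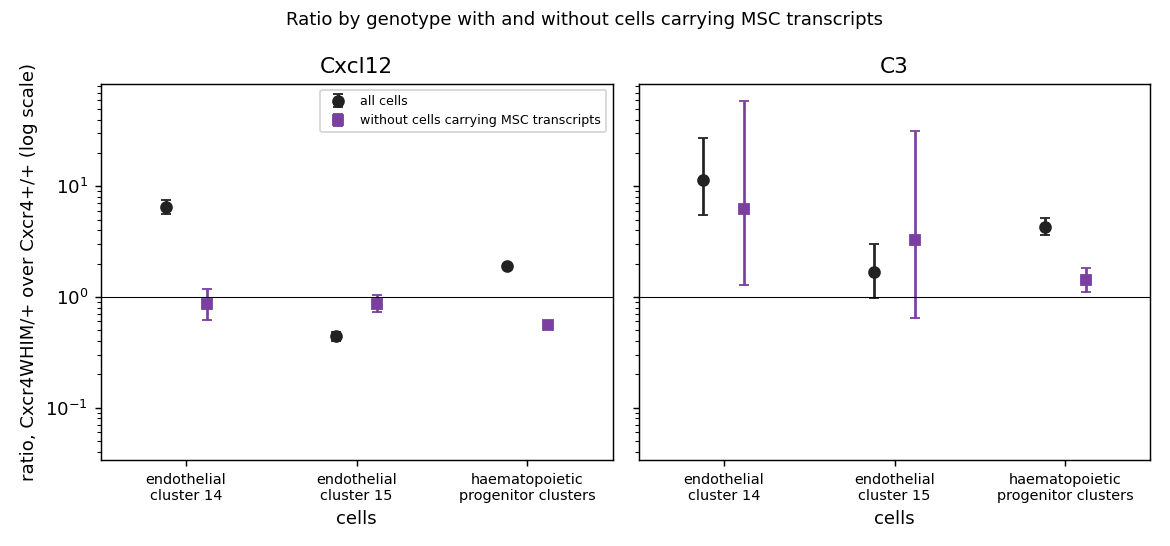
Ratio of Cxcr4WHIM/+ over Cxcr4+/+ for Cxcl12 and C3 in endothelial clusters 14 and 15 and in the haematopoietic progenitor clusters, with all cells and without cells carrying at least 2 of Adipoq, Lepr, Cxcl14 and Hp. The axis is logarithmic; bars are exact 95% conditional intervals, which hold counting error only.

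Genes higher in Cxcr4WHIM/+ endothelial-like cells were the intermediate filament gene Vim (558 and 1442 CPM, 2.58, 2.27–2.95), the fatty acid-binding Fabp5 (146 and 389 CPM, 2.67, 2.07–3.47), the interferon-induced Ifi27l2a (12.3 and 64.9 CPM, 5.28, 2.34–13.97) and Tspan13 (100.0 and 269 CPM, 2.69). C1qtnf9 (45.6 and 182 CPM, 3.98), the aquaglyceroporin gene Aqp7 (28.1 and 107 CPM, 3.81), Car8 (14.04 and 61.6 CPM, 4.39) and Mustn1 (15.8 and 64.9 CPM, 4.11) had no UMIs in cluster 14. AA467197 (7.02 and 56.8 CPM, 8.08, 2.89–31.3, on 4 and 35 UMIs) and Tppp3 (14.04 and 61.6 CPM, 4.39) completed the list. Lower were the nuclear receptor gene Nr4a1 (333 and 126 CPM, 0.379, 0.288–0.496), Nr1d2 (79.0 and 25.9 CPM, 0.328), the autophagy kinase gene Ulk1 (96.5 and 35.7 CPM, 0.370), Thbs1 (82.5 and 27.6 CPM, 0.334), Mt1 (160 and 69.7 CPM, 0.437), the ERK phosphatase gene Dusp6 (193 and 90.8 CPM, 0.470), Shank3 (255 and 125 CPM, 0.491), Fosl2 (344 and 180.0 CPM, 0.523), Noct (0.420), Pitpnm2 (0.344) and Adpgk (0.308). Osteopontin, encoded by Spp1, was 237 and 84.3 CPM (0.356, 0.253–0.493), with 1.49 in cluster 14 and 0.152 in cluster 15. Only cluster 15 had enough cells for the check by cluster, and it made up 49.4 and 58.3% of the class. In cluster 14 Vim was 1.17 and Fabp5 1.06 (2.43 and 2.77 in cluster 15), and Ifi27l2a and Tppp3 had no UMIs there in Cxcr4WHIM/+. Ratios came nearer 1 for Ifi27l2a (2.71) and Nr1d2 (0.497) in thinned cells, for Mt1 (0.902) at 20% mitochondrial UMIs and for Spp1 (0.870) at resolution 0.5. They went further from 1 for Aqp7 (18.0) and C1qtnf9 (11.1) in thinned cells, for Mustn1 (24.6) and C3 (10.4) at resolution 0.5 and for Thbs1 (0.142) at 5% mitochondrial UMIs.

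**Figure D3:**
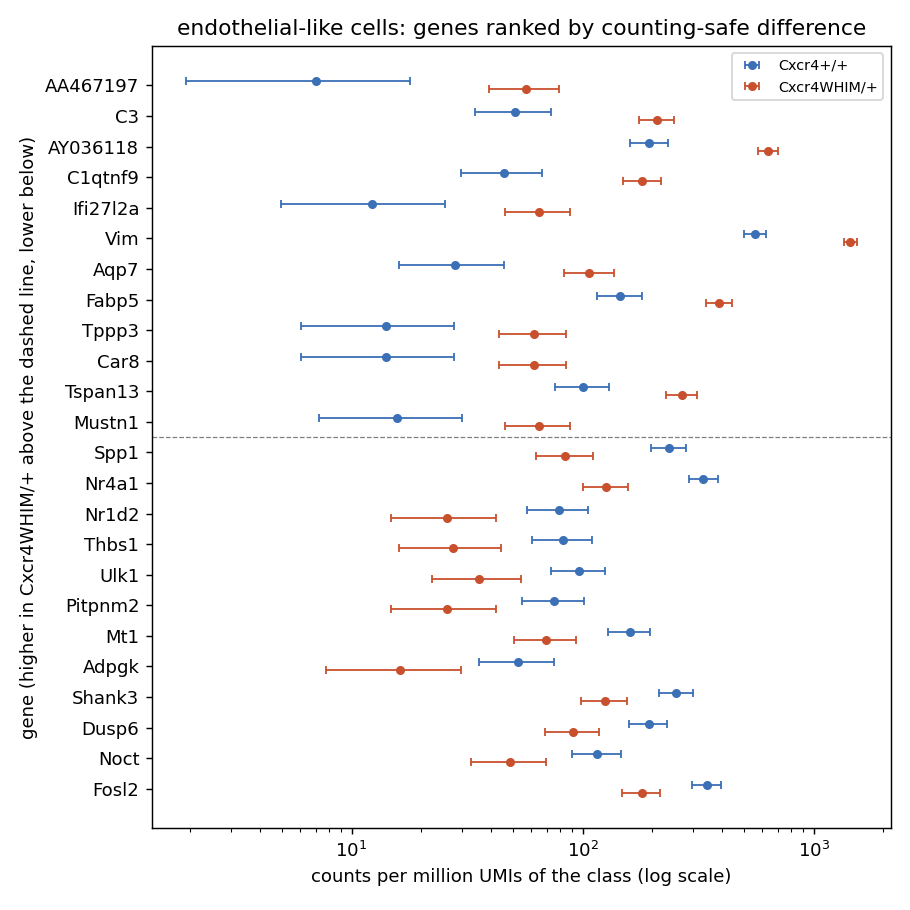
Expression of 24 named genes in endothelial-like cells of the Cxcr4+/+ and the Cxcr4WHIM/+ library. Dots are CPM summed over the cells of 1 library, on a logarithmic axis; bars are exact 95% Poisson intervals, which hold counting error only.

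Of 28 lists with enough genes in endothelial-like cells, 4 lay above and 5 below the random range. Interferon-stimulated genes were higher (5 higher, 0 lower and 14 neither, median 0.36, percentile 99.99), with Isg15 at 82.5 and 186 CPM (2.26, 1.60–3.25), Gbp7 at 40.4 and 85.9 CPM (2.13), Iigp1 at 167 and 264 CPM (1.59) and Ifitm3 at 2740 and 3550 CPM (1.30). MHC class I genes were higher as a group (1 higher, 0 lower, 14 neither, 0.30, percentile 99.97), with H2-K1 at 2117 and 2668 CPM (1.26) and Psmb9 at 98.3 and 157 CPM (1.60). Both medians were larger without carrying cells (0.43 and 0.37); by cluster the interferon list was 0.03 in cluster 14 and 0.46 in cluster 15, and MHC class I 0.19 (percentile 95.6) and 0.27 (percentile 99.1). The median of acute phase and complement in endothelial-like cells was above the range (3 higher, 0 lower and 9 neither, 0.42), but it was −0.0435 in thinned cells and −0.0386 without doublet removal. Below the range were immediate early genes (0 higher, 2 lower and 20 neither, −0.33, percentile 0), with Nr4a1, Fos (2777 and 1829 CPM, 0.659) and Fosb (985 and 657 CPM, 0.667). By cluster the immediate early list was −0.52 (percentile 0) in cluster 14 and 0.04 (percentile 53.3) in cluster 15, although Nr4a1 was lower in both (0.349 and 0.406). TNF targets (2 higher, 3 lower and 7 neither, −0.29, with −0.40 in cluster 14 and −0.03 in cluster 15; Icam1 384 and 243 CPM, 0.633), unfolded protein response genes (0 higher, 1 lower and 15 neither, −0.23; Calr 890 and 598 CPM, 0.672), BMP and TGF-beta signalling (1 higher, 1 lower and 13 neither, −0.24; Bambi 225 and 133 CPM, 0.592) and sinusoidal scavenger genes (0 higher, 2 lower and 9 neither, −0.35; Stab2 695 and 433 CPM, 0.623, and Ehd3 160 and 82.7 CPM, 0.518) followed. The sinusoidal list was −0.19 (percentile 11.9) within cluster 14, which itself made up less of the Cxcr4WHIM/+ endothelial-like cells. Inside the range were lymphotoxin beta receptor (−0.31, with −0.70 at percentile 0.03 in cluster 14), heat shock (−0.08, with −0.33 at percentile 0.87 in cluster 14 and 0.06 in cluster 15), p53 (−0.14), adipogenic (−0.01), osteogenic (0.10), collagen and matrix (0.03), basement membrane (0.10; Sparcl1 153 and 313 CPM, 2.05), Wnt (−0.02), Notch (−0.28, percentile 4.11, with −0.61 at percentile 0.13 in cluster 15), adhesion (−0.07), VEGF (−0.09), hypoxia (0.08, with 0.25 at percentile 99.3 in cluster 15), oxidative phosphorylation (0.07), S phase (−0.01), G2 and M phase (−0.07), glucocorticoid (−0.23), ribosomal (0.11) and mitochondrially encoded genes (0.04). Without carrying cells Notch (−0.38, percentile 1.29) and hypoxia genes (0.27, percentile 99.8) lay outside the range. Unfolded protein response genes then lay inside it (−0.20, percentile 6.54). With all cells they were inside it in cluster 14 (−0.13, percentile 22.9) and in cluster 15 (−0.18, percentile 16.4) alone. MHC class II and cholesterol genes had fewer than 3 measured members.

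**Figure D4:**
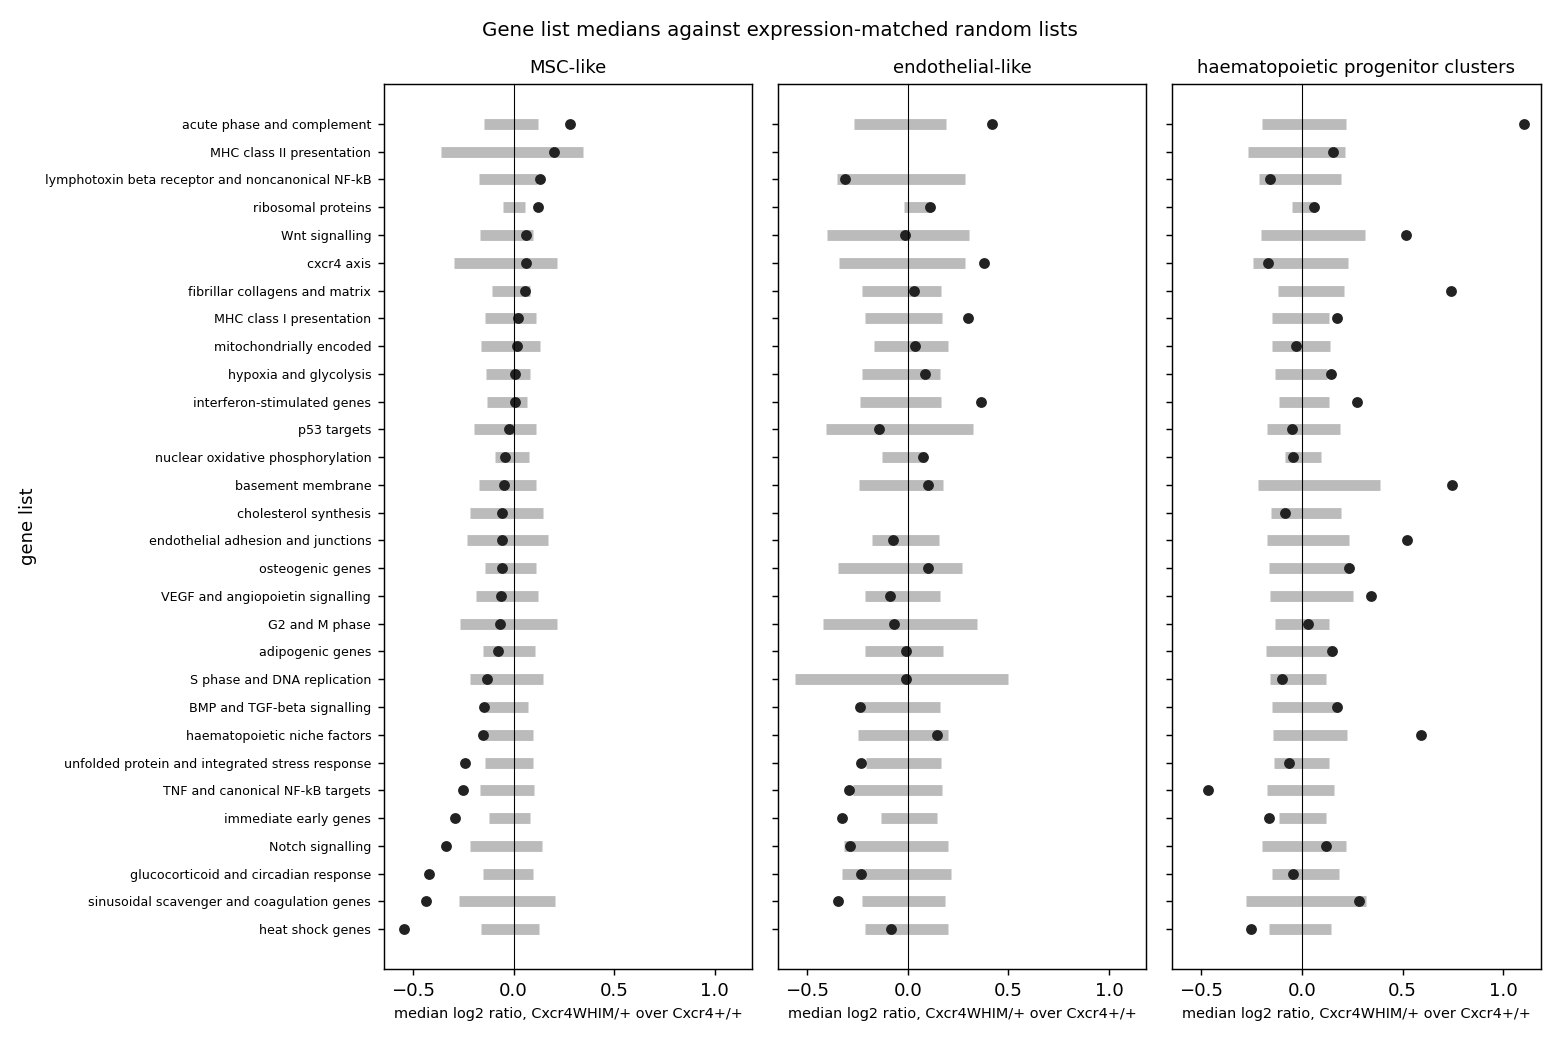
Median log2 ratio of Cxcr4WHIM/+ over Cxcr4+/+ for the fixed gene lists in MSC-like cells, endothelial-like cells and the haematopoietic progenitor clusters. Dots are list medians; grey bars span the central 95% of 10000 expression-matched random lists and describe these libraries, not replicate spread.

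Set side by side, MSC-like and endothelial-like cells had part of the difference in common. C3 (log2 1.69 and 2.04), AY036118 (1.52 and 1.71) and Lars2 (0.89 and 1.06) were higher in both. They were higher in the haematopoietic progenitor clusters too (2.10, 2.32 and 0.84), so AY036118 and Lars2 were not particular to these classes. C3 there was 10.6 and 45.2 CPM, but 8.27 and 11.7 CPM (ratio 1.42, 1.12–1.81) without cells carrying MSC transcripts. Much of its difference in those clusters thus lay in carrying cells. Most endothelial C3 lay in cells carrying MSC transcripts, since 29 and 129 UMIs became 4 and 17 without them. Between these classes, Socs2 (−1.69 and 0.11), Cxcl1 (−1.43 and 0.54) and Hspb1 (−1.23 and 0.28) were lower only in MSC-like cells. Srgn (1.59 and 0.18) and Tmem86a (1.44 and 0.08) were higher mainly in MSC-like cells. In the haematopoietic progenitor clusters Hspb1 was lower as well (−0.85) and Tmem86a higher (0.76), while Socs2 was 0.58, Cxcl1 −0.24 and Srgn 0.24. Vim (0.24 and 1.37), Fabp5 (−0.60 and 1.42) and Bmp6 (−0.00 and 1.34) were higher in endothelial-like cells, Vim and Fabp5 mainly in cluster 15 and Bmp6 not after thinning (ratio 1.08), and Dusp6 went opposite ways (0.67 and −1.09). Of 43 named genes measured in both, 28 had the same sign and 22 had intervals that did not overlap. The list medians of endothelial-like minus MSC-like cells were 0.46 for heat shock, 0.36 for interferon-stimulated and −0.44 for lymphotoxin beta receptor genes. Over 4022 genes the log2 ratios of the classes correlated with r of 0.308; r was 0.416 for MSC-like cells with the haematopoietic progenitor clusters and 0.337 for endothelial-like cells with them, so log2 ratios also went together with a class outside the stroma and endothelium.

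Osteolineage-like cells were 7.42% (6.72–8.16) and 9.16% (8.48–9.88) of MSC-like and osteolineage-like cells together. The order of their shares of kept cells depended on the setting, with 1.49 and 1.38% at 5% mitochondrial UMIs and 3.44 and 3.32% with no list left out of clustering. Their cluster 5 made up 83.6 and 91.2% and cluster 22 16.4 and 8.84%. Cxcr4 was 1.97 and 4.31 CPM (2.19, 0.627–11.7), Cxcl12 10899 and 13914 CPM (1.28, 1.254–1.299) and Kitl 493 and 626 CPM (1.27). Within cluster 5 Cxcl12 was 1.04 and Kitl 1.05 (0.964–1.14), and within cluster 22 0.762 and 0.597 (0.307–1.14), so the pooled ratios went with the smaller part of cluster 22 in Cxcr4WHIM/+. C3 was higher here as well (277 and 1131 CPM, 4.07, 3.69–4.51), with the complement protease gene C1s1 (111 and 258 CPM, 2.33), haptoglobin, Hp (1456 and 2791 CPM, 1.92), and Lrg1 (3.28 and 14.8 CPM, 4.52, 1.82–14.5). Summed MSC markers were also higher in this class (5751 and 8117 CPM, 1.41). The chemokine genes Cxcl10 (12.5 and 66.3 CPM, 5.32, 3.33–8.99) and Cxcl13 (2.62 and 31.0 CPM, 11.8, 4.49–44.1), the interferon-induced Ifit3 (10.5 and 35.6 CPM, 3.39) and Bst2 (442 and 726 CPM, 1.64) and the Wnt antagonist genes Dkk1 (7.22 and 23.5 CPM, 3.25) and Sfrp1 (95.1 and 178 CPM, 1.87) were higher. The fixed collagen and matrix list lay inside the random range (3 higher, 7 lower and 22 neither, 0.04), but abundant bone collagen and osteocalcin genes were lower: Bglap (36972 and 17205 CPM, 0.465), Bglap2 (16051 and 7317.5 CPM, 0.456), Col1a1 (39605 and 19754 CPM, 0.499), Col1a2 (21269 and 10100 CPM, 0.475) and Col11a2 (1162 and 419 CPM, 0.360). Summed chondrocyte markers were lower beside them (562 and 173 CPM, 0.307). Bglap and Bglap2 are near-identical copies whose split is uncertain. Within cluster 22 the ratios of Bglap and Col1a1 were 0.925 and 0.965, and within cluster 5 0.679 and 0.923. The smaller part of cluster 22 in Cxcr4WHIM/+ thus carried much of the gap in these genes. The fixed osteogenic list, by contrast, had a median of −0.46 within cluster 5 alone (percentile 0, 0 higher, 6 lower and 19 neither), close to the pooled class.

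In osteolineage-like cells 4 of 29 lists lay above and 4 below the random range. Acute phase and complement genes (7 higher, 0 lower and 8 neither, median 0.56, percentile 100), interferon-stimulated genes (8 higher, 0 lower and 21 neither, 0.34, percentile 99.96), MHC class I genes (0.35, percentile 99.8) and Wnt signalling (5 higher, 1 lower and 11 neither, 0.30, percentile 99.2) were above. Immediate early genes (1 higher, 15 lower and 9 neither, −0.63, percentile 0) were below, with Ier3 at 150 and 58.0 CPM (0.387), Fosb at 402 and 168 CPM (0.419), Jun at 487 and 206 CPM (0.424) and Fos at 1080 and 503 CPM (0.466). Osteogenic genes (1 higher, 10 lower and 15 neither, −0.46, percentile 0) and heat shock genes (0 higher, 3 lower and 11 neither, −0.22, percentile 0.20) were below as well; Hspa1a was 93.2 and 43.1 CPM (0.463). Ribosomal protein genes were just below (0.06, percentile 2.14). With the clusters weighted by mean share, the acute phase list stayed above (0.32, percentile 99.98) and immediate early (−0.70), osteogenic (−0.23) and heat shock genes (−0.25) below, joined by collagens and matrix (−0.10). The interferon (0.09, percentile 95.6), MHC class I (0.11, percentile 83.7), Wnt (0.13) and ribosomal lists (0.10) lay inside. Haemoglobin transcripts of red cells were 3040 and 46.6 CPM in this class.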

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

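All 7 tests weighed below were chosen after the results they concern had been seen. The runs by cluster and the settings of the clustering were planned, and the run without cells carrying MSC transcripts was not.

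C3 was higher in Cxcr4WHIM/+ MSC-like cells (3.22), while C3 is also a leading gene of the clusters that this library mostly filled. A different mix of clusters as the whole cause was argued against, because the ratio with clusters weighted by mean share was still 2.29. The lower bound used, 2.24, took the relative width of the pooled interval, so it is not the weighted ratio's own interval. Fibroblast-like cells of Cxcr4WHIM/+ held 1048 CPM of C3, under the 2113 CPM of the MSC-like cells. The added 1458 CPM would need a fibroblast share of 139%, so admixture of such cells cannot account for all of it. The gain in summed fibroblast markers (123 CPM, upper bound 139) could not decide this. Its needed 7113 CPM lies above the 5112 CPM of fibroblast-like cells themselves. C3 was also higher in osteolineage-like cells (4.07), which were clustered apart. An effect of the WHIM allele on stromal cells and an effect of the tube on them may each explain it, and 1 library per genotype left both open.

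Heat shock (−0.55) and immediate early genes (−0.29), which respond to warming and dissociation, were lower in Cxcr4WHIM/+ MSC-like cells. With clusters weighted by mean share the immediate early median was 0.00504 (percentile 66.0), so a different mix of clusters is a candidate explanation for that list. Clusters 2, 3, 4 and 6 were each mostly of 1 library, so the weighting cannot tell that mix from a library-wide difference. The heat shock median stayed at −0.44 (percentile 0) under the same weighting, which argues against the mix of clusters as the whole cause. Heat shock genes were lower in the haematopoietic progenitor clusters too (−0.25, percentile 0.12), the value an effect on the whole tube would need. That class was not weighted by cluster, so its mix of clusters may carry part of the value. In endothelial-like cells the list was −0.33 (percentile 0.87) in cluster 14 and 0.06 in cluster 15. In cluster 15 and in the pooled endothelial-like class (−0.08, percentile 15.95) the list lay inside the random range. A difference in handling could explain the lower values, but alone it would not account for their absence in cluster 15. An effect of genotype was not tested.

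MSC markers were higher in the haematopoietic progenitor clusters of Cxcr4WHIM/+ (265 and 519 CPM; 1.96). Within a sample 1 source keeps its genes' counts in 1 ratio in every type, and free RNA reaches every droplet. Without the richest 5% of cells of each library the markers were 148 and 118 CPM (0.796, 0.749–0.847), which argues against free RNA as the whole cause. The richest 5% held 78.9% (78.1–79.7) of the marker UMIs in Cxcr4WHIM/+ and 46.5% (44.9–48.1) in Cxcr4+/+, where an even spread gives 8.79 and 13.3%. Droplets holding an MSC and a blood cell remain a candidate explanation, although fewer doublets were called in Cxcr4WHIM/+ (2.21%) than in Cxcr4+/+ (3.71%).

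Haematopoietic progenitor clusters made up 32.9% (31.9–33.8) of Cxcr4+/+ and 26.2% (25.3–27.1) of Cxcr4WHIM/+ kept cells, outside the planned comparisons, although the gates excluded CD45 and lineage antigens.

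Endothelial clusters 14 and 15 lay outside the random range on opposite sides in 4 lists, and the differences between them (15 minus 14, log2) were not tested. Summed MSC markers went the same opposite ways (776 and 3199.6 CPM, ratio 4.12, in cluster 14 and 2295 and 1528 CPM, 0.666, in cluster 15), as did osteolineage markers (3.31 and 0.363). Niche factors were 0.76 and −0.69 (−1.45), and 0.07 and 0.03 without carrying cells. Acute phase and complement genes were 2.22 and −0.71 (−2.93). Without carrying cells that list was −0.10 (percentile 38.7, on 3 members) in cluster 15, and its 2 measured members in cluster 14 were too few for a median. Osteogenic genes were 1.06 and −1.09 (−2.15), with Spp1 at ratios of 1.49 and 0.152, and without carrying cells only 1 member was measured in each cluster. Collagen and matrix genes were 1.33 and −0.74 (−2.07), and 0.21 and −0.57 without carrying cells, which were 16.0 and 28.4% of cluster 14 and 10.7 and 10.6% of cluster 15.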

How the results depend on the processing

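No paired analysis was possible because the genotypes share only the replicate number 1, which pairs no animals. The carrying-cell run and osteolineage weighting were chosen after the results had been seen, the other settings before. Gene ratios stayed the same in 1018 runs, moved outside the counting interval of the reported ratio in 139 and reversed in 1. List medians stayed inside the interval of their median in 835, moved outside it in 13 and reversed in 5. A gene was counted as reversed only if its reported interval excluded 1, and a list only if it lay outside the random range. Values near no difference crossed it more often: Bmp6 in MSC-like cells lay on its reported side in 2 of 12 alternatives and the Cxcr4 axis list there in 8 of 14. Over all settings C3 in MSC-like cells ranged from 2.29 to 3.28, Socs2 from 0.287 to 0.316 and the heat shock list from −0.57 to −0.44. In endothelial-like cells the interferon list ranged from 0.31 to 0.46, the immediate early list from −0.37 to −0.19 and Spp1 from 0.248 to 0.870. Interferon-stimulated, MHC class I and immediate early genes of endothelial-like cells lay outside the random range in each alternative run of the pooled class, though not in each cluster alone.

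Immediate early genes in MSC-like cells reversed to 0.00504 with clusters weighted by mean share and to 0.0316 with no list left out of clustering. Without carrying cells Cxcl12 in endothelial-like cells turned to 0.962, acute phase and complement in endothelial-like cells to −0.41 (on 6 instead of 12 members, and with Hp both in the list and among the genes that mark carrying cells), and the correlation, MSC-like against endothelial-like genotype difference, was 0.249 over 3198 genes (0.380 over 927 genes with at least 200 UMIs). That acute phase list was −0.0435 in thinned cells, −0.0386 with no doublet removal and 1.78 at resolution 0.5; the cause was not tested. Of the 24 genes named in MSC-like cells 14 were named again with no list left out. Of the 24 in endothelial-like cells, 7 were named again with at least 200 UMIs, 14 by the mean over cells, 8 after thinning, 14 without doublet removal and 12 at resolution 0.5. Lists outside the random range numbered 4 instead of 9 in endothelial-like cells after thinning, and 5 instead of 8 in osteolineage-like cells with clusters weighted.

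The order of MSC-like shares (Cxcr4+/+ then Cxcr4WHIM/+) turned at 500 UMIs (52.1 and 48.3%), 5% mitochondrial UMIs (53.6 and 50.4%), 20% mitochondrial UMIs (53.3 and 49.8%) and with no list left out (52.3 and 41.4%). In each of these a cluster with MSC as its best list stayed unnamed, with 1.19 and 12.7, 2.29 and 13.8, 1.58 and 13.2, and 1.80 and 21.1% of cells. MSC-like shares were 47.7% of Cxcr4+/+ at 2000 UMIs, 51.4 and 58.4% without doublet removal and 58.7% of Cxcr4WHIM/+ at resolution 2. Endothelial-like shares were 1.91 and 1.55% at 2000 UMIs. Osteolineage-like shares were 3.69 and 4.79% at 500 UMIs, 1.49 and 1.38% at 5% and 2.81 and 2.97% at 20% mitochondrial UMIs, 3.44 and 3.32% with no list left out, 3.77% of Cxcr4+/+ at resolution 0.5 and 7.14% of Cxcr4WHIM/+ at resolution 2; the cause was not tested.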

Other observations

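The haematopoietic progenitor clusters fell outside the planned comparisons and held cells with distinct leading genes: Rgs1, Myct1 and Hlf in cluster 9, Pf4 and Gata2 in cluster 10, Ccl4, Mpo and Ctsg in cluster 11, Ly6d, Dntt and Flt3 in cluster 12, Tyrobp and Mpo in cluster 13, and Car1, Myb and Gata2 in cluster 18. Cxcr4 was lower in the Cxcr4WHIM/+ library here (129 and 89.8 CPM; 0.695, 0.651–0.743). A Cxcr4 UMI was found in 34.5 and 34.1% of these cells, and in 19.9% (18.5–21.4) and 14.9% (13.6–16.3) after thinning (46 and 23 cells left out, median depth 4066 and 6237 UMIs). By cluster, Cxcr4 was 142 and 97.2 CPM in cluster 9 (0.685, 0.605–0.776), 164 and 140.3 in cluster 12 (0.856, 0.747–0.980) and 43.4 and 48.0 in cluster 18 (1.11, 0.772–1.59), with ratios under 1 in the other 3. T- and NK-like cells had 224 and 131 CPM (0.584, 0.380–0.892). The lymphoid-marked cluster 12 was 27.4 and 14.2% and cluster 9 29.3 and 42.6% of these cells. No weighting by cluster was run for this class, so its pooled ratios and list medians may carry this difference in mix.

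TNF and canonical NF-kB targets were lower in these clusters (0 higher, 8 lower and 9 neither, median −0.46, percentile 0), with Nfkbiz at 136 and 58.2 CPM (0.428) and the inhibitor gene Nfkbia at 457 and 280 CPM (0.611). Interferon-stimulated genes were higher (6 higher, 1 lower and 25 neither, 0.28, percentile 100), with Iigp1 at 8.84 and 18.3 CPM (2.07), Rtp4 at 17.5 and 30.8 CPM (1.76) and Ifitm3 at 671 and 949 CPM (1.41), and MHC class I genes too (0.18, percentile 99.7). Proliferation lists lay inside the range: G2 and M phase genes had 2 higher, 0 lower and 23 neither (0.03, percentile 64.7; Ube2c 1.62) and S phase genes 0 higher, 2 lower and 18 neither (−0.10, percentile 11.3; Uhrf1 0.624). Without cells carrying MSC transcripts the TNF and interferon medians were close to these values (−0.57 and 0.28), while MHC class I was inside the range (0.13, percentile 97.1). Acute phase, niche and collagen lists, at 1.10, 0.59 and 0.74 with all cells, were −0.04, −0.51 and −0.46 without them (Hp is an acute phase gene and also marks carrying cells), and Cxcl12 went from 1.90 to 0.556. Cxcr4WHIM/+ cells were deeper here (median 6237 against 4066 UMIs), so the rule flagged them more readily. Lepr (0.206) and Adipoq (0.550) were under 1 afterwards too. Values under 1 without carrying cells cannot be told apart from unequal removal.

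The interferon list lay above the range in endothelial-like cells, in osteolineage-like cells (inside it with clusters weighted, 0.09) and in the haematopoietic progenitor clusters. Of the endothelial clusters only cluster 15 was above (0.46), with cluster 14 inside the range (0.03, percentile 65.0). In MSC-like cells the list was 0.01, and the difference between classes was not tested. Heat shock medians were lower in MSC-like and osteolineage-like cells, the haematopoietic progenitor clusters and endothelial cluster 14 (−0.55, −0.22, −0.25 and −0.33), but not in endothelial cluster 15 (0.06). Xist gave 22 and 48 UMIs and Y-linked genes 6666 and 9081. MSC markers were detected in at least 25% of the cells for 9 or 10 of 10 genes in the plasma-cell-like, neutrophil-like and erythroid-like clusters and megakaryocyte-like cluster 17, and for 1 in each haematopoietic progenitor cluster.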
